A study of Ovis aries with 6 samples.

How the data were processed

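The samples are genomic DNA from perirenal adipose tissue of 3 sheep fetuses and 3 lambs, sequenced as whole-genome bisulfite libraries with 1 lane of paired 100-base reads per animal, per the labels' protocols. In this assay bisulfite turns unmethylated cytosine into a base read as T, so the share of reads that still show C at a CpG is its methylation level. Reads were mapped to the sheep build Oar_v3.1 per the series design text. The submitters' processing notes name BWA, Picard and the builds Oar_v3.1 and hg19 without saying what each was used for, and the methylation caller and the duplicate and conversion filters are not given in the sources used here. The table deposited by the authors holds raw counts per CpG position, methylated and covering reads for each animal, with columns matched to animals by the sample descriptions. Those descriptions end in TV for each fetal animal and in VEH for each lamb, so whatever the tags stand for cannot be told apart from stage. The table lists 26377052 positions, no 2 of them 1 base apart, so strands appear to be combined. The authors also deposited region lists of positions alone: DMRs in a hyper and a hypo list, and UMRs, LMRs and DMVs in 1 list per stage. How those lists were called is not given in the sources used here; DMV ends fall on a grid of 50 bases and no DMV is shorter than 5 kb.

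Positions on unplaced contigs (431716) were left out, and the comparisons used autosomes 1 to 26. A CpG entered when each of the 6 animals had at least 5 reads, a minimum set before the data were examined, as were the tests, the alternatives and the rule for naming regions. The level of a class of regions is the sum of methylated reads over the sum of covering reads per animal, compared by an exact permutation test, two-sided. DMVs, UMRs outside DMVs and LMRs outside both were formed from the lists of both stages merged. Non-overlapping 1 kb windows, merged UMRs and LMRs, and the authors' DMRs were tested when they had at least 3 usable CpGs. The test was a logistic model of methylated against unmethylated reads, quasi-binomial, lamb against fetal, two-sided, with the dispersion moderated over regions as in limma's squeezeVar and not allowed below 1, and Benjamini-Hochberg adjustment within each set of regions. A region was called at an adjusted p under 0.05 and a difference of at least 10 percentage points between the means of the animals' levels. The prior dispersion and its degrees of freedom were 1.43 and 8.99 for UMRs and LMRs, the same as limma's own function gave. Windows and UMRs or LMRs were to be named when called and without overlap between the animals of the stages, up to 10 windows and 12 UMRs or LMRs per direction, and DMRs as the 10 per direction with the largest differences without overlap. As no gene annotation of Oar_v3.1 was used here, regions are named by position, and the planned tests of promoters and of gene lists were not run.

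The test was tried on simulated data, with reads drawn on the real regions and 200 regions shifted by 10 to 40 points. False calls were 0 among the 842371 windows and 0 among the 78794 UMRs and LMRs left unshifted, and 1 among the 76 DMRs left unshifted. Of shifts of 30 points it called 0% in windows, 12% in UMRs and LMRs and 92% in DMRs. In the DMRs few regions share the adjustment and 200 of 276 were shifted, and the effects of the 2 were not separated. The simulated spread fell short of the real one in windows and in UMRs and LMRs. The prior dispersion was set at 1.28 and 1.43 there and found at 1.18 and 1.29. For these 2 sets the false calls may be understated and the shares called overstated. Reads are not marked by molecule, so counting precision covers counting error alone. The alternatives were coverage minimums of 3 and 10 reads, leaving out each animal, leaving out CpGs with over 3 times the median summed coverage of 41 reads, equal weight per CpG, other minimums of difference and of CpGs per region, windows of 500 bases and 2 kb, limma on log2 of methylated over unmethylated reads with a pseudocount of 1, edgeR's quasi-likelihood test on both kinds of reads with a term per animal, the replicate number as a block, and 50% reciprocal overlap of lists. A coverage minimum of 1 read, a dispersion allowed below 1, regions listed in both stages alone, regions away from chromosome ends and the test of single DMVs were added after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16.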

Results

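DNA methylation was measured by whole-genome bisulfite sequencing in perirenal adipose tissue, the fat depot around the kidney, of 6 pure-bred Merino sheep. The 3 fetal animals were taken at 132 days post conception, before term at 150 days, and their tissue is labelled brown adipose. The 3 lambs are labelled 89 days after birth in the sample protocols and 80 days in the series design text, and their tissue is labelled white adipose. The fetuses came from 3 ewes and the lambs from 3 others, so each sample is a separate animal. Brown adipose tissue burns fuel for heat around birth, and white adipose tissue stores fat; the series title gives the transition between them as its subject, and the comparison of the stages asks where CpG methylation differs. Reads covering CpG positions totalled 192795449, 139053472 and 170586238 in fetal animals 1 to 3, and 207030752, 135180508 and 144795518 in lambs 1 to 3. Read totals here and below are sums over CpG positions, so a read is counted once at each CpG it covers. Mean coverage of an autosomal CpG ran from 5.22 reads in lamb 2 to 8.00 in lamb 1. With at least 5 reads in each of the 6 animals, 6163112 of 24936679 autosomal CpG positions entered the comparisons, and the regions tested carried a median of 41.8 reads per animal for 1 kb windows. All positions are on the sheep build Oar_v3.1.

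Methylation of the genome as a whole was close in both stages, while with a coverage minimum of 5 reads the classes of regions with low methylation stood higher in each of the lambs than in each of the fetuses. Low-methylated regions (LMRs), short stretches of intermediate methylation that often mark distal regulatory elements, were at 33.1% ± 0.796 in fetal tissue and 34.7% ± 0.654 in lamb tissue (SD, n = 3 each), a difference of 1.55 percentage points. DNA methylation valleys (DMVs), long unmethylated stretches that often hold developmental regulator genes, were at 5.72% ± 0.201 and 6.62% ± 0.267, a difference of 0.897 points. Unmethylated regions (UMRs) outside DMVs, which include most CpG-rich promoters, were at 12.1% ± 0.183 and 12.5% ± 0.102, a difference of 0.410 points. In these 3 classes the exact permutation test, two-sided, gave p = 0.1, the smallest value that 3 animals against 3 allow, so the design cannot pass 0.05. The levels of the stages overlapped in LMRs when CpGs of high coverage were left out (1.47 points) and when each CpG had equal weight (1.45 points; exact permutation p = 0.2 for both). They overlapped in UMRs with a minimum of 1 read (0.370 points, exact permutation p = 0.2). All autosomal CpGs together were at 71.2% ± 0.107 in fetal and 71.9% ± 1.05 in lamb animals (SD, n = 3 each; exact permutation p = 0.4), and the autosomes outside the listed regions at 79.4% ± 0.197 and 79.8% ± 1.06 (exact permutation p = 0.6). The genome-wide difference of 0.680 points fell within the spread of the lambs, and was 0.191 points without lamb 2, the animal with the highest level at 72.9%; outside the listed regions the difference was then -0.0408 points. Without lamb 1, the lowest of the lambs, the genome-wide difference was 1.23 points (exact permutation p = 0.1, the smallest value that 3 animals against 2 allow). Among 1 kb windows grouped by CpG number, no group gave an exact permutation p under 0.4 (two-sided), and the windows with over 40 CpGs were at 46.6% in fetal and 46.2% in lamb tissue. With at least 10 reads in each animal only 29803 CpGs remained, and the difference was 0.192 points in DMVs, 1.84 in UMRs and 2.47 over all autosomal CpGs, with overlap between the stages in DMVs (exact permutation p = 0.8) and in LMRs (exact permutation p = 0.4).

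**Figure D1:**
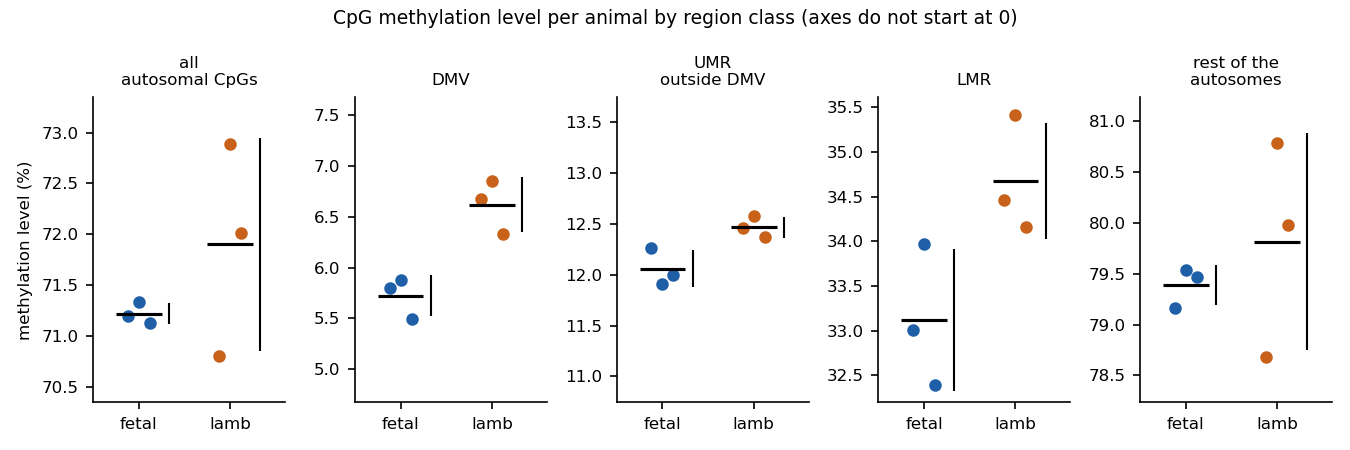
Methylation level in percent (y axis, not starting at 0) of each fetal and lamb animal over all autosomal CpGs, in DMVs, in UMRs outside DMVs, in LMRs and in the rest of the autosomes; points are animals, horizontal lines means and vertical lines ± SD with n = 3. In DMVs the fetal animals lie between 5.50% and 5.88% and the lambs between 6.33% and 6.85%, while over all autosomal CpGs lamb 1 at 70.8% is below the fetal animals.

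The stages shared most of their UMRs and DMVs and fewer of their LMRs. Of the autosomal UMRs listed for fetal tissue, 92.7% overlapped a lamb UMR by at least 1 base, and 94.1% of the lamb UMRs overlapped a fetal one. For LMRs the shares were 68.8% of 108524 fetal and 72.2% of 103520 lamb regions. Of 512 fetal DMVs 80.5% overlapped a lamb DMV, and of 461 lamb DMVs 91.1% overlapped a fetal one. LMRs with no UMR or LMR of the other stage numbered 31855 for the fetal list and 26223 for the lamb list. Inside the fetal-only LMRs the level was 38.5% ± 1.33 in fetal and 49.1% ± 1.31 in lamb animals, and inside the lamb-only LMRs it was 48.7% ± 0.636 and 39.4% ± 0.511 (SD, n = 3 each). Those regions were listed because the level was low in the stage concerned, so these differences are not independent of the lists. LMRs present in both lists were at 29.7% ± 0.729 in fetal and 31.2% ± 0.587 in lamb animals, UMRs in both at 10.3% ± 0.164 and 10.7% ± 0.0896, and DMVs in both at 5.53% ± 0.219 and 6.48% ± 0.234 (SD, n = 3 each; exact permutation p = 0.1 for each). The lists hold 1 set per stage, so the overlaps carry no replicate error.

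Over windows fixed without regard to any list, no single 1 kb window could be called different between the stages. None of 842571 autosomal windows reached an adjusted p under 0.05 in the quasi-binomial test with limma's moderation of the dispersion, and limma and edgeR on the same reads also gave 0. An unadjusted p under 0.05 was found for 51510 windows, or 6.11%, against 47612 with limma and 45958 with edgeR, and 57.5% of the 51510 had the higher level in lambs. The smallest adjusted p was 0.0981, shared by several windows. Among them, chosen after its values were seen, the window at chromosome 3 from 221005001 to 221006000 was at 42.8% ± 4.06 in fetal and 71.8% ± 4.48 in lamb animals (SD, n = 3 each), over 146 reads per animal. In simulated reads on these windows, with 200 of them shifted, 4% of shifts of 40 points and 0% of shifts of 30 points were called, so a large difference limited to few windows would seldom be called. The count was 142 windows, 94 higher and 48 lower in lambs, with a coverage minimum of 3 reads, and 25 with 2 kb windows.

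Among the UMRs and LMRs, 3 regions were called different, 2 of them higher and 1 lower in lambs. The region on chromosome 7 from 99045977 to 99046242, an LMR of the fetal list over 5 CpGs, was at 23.7% ± 3.16 in fetal and 80.0% ± 0.807 in lamb animals. The region on chromosome 21 from 34496770 to 34496996, also a fetal LMR, was at 24.9% ± 9.30 and 76.6% ± 6.65, and lies in a DMR of the hyper list. The region on chromosome 7 from 97896783 to 97897284, an LMR of the lamb list over 12 CpGs, was at 66.2% ± 2.09 and 27.6% ± 8.45 (SD, n = 3 each), and lies in a DMR of the hypo list. Their adjusted p values over 78994 tested regions were 0.0236, 0.0496 and 0.0496 in the quasi-binomial test with limma's moderation. Each of the 3 is an LMR in 1 stage only, so its listing already reflects the difference. An unadjusted p under 0.05 was found for 8890 regions, or 11.3%, of which 63.5% had the higher level in lambs. In regions listed in both stages the share was 8.90% of 63450, with 0 calls. The 15544 regions listed in 1 stage, tested and adjusted by themselves after the data were seen, gave 111 calls, but they were picked for a low level in that stage, so this count is not independent of the lists. Leaving out any animal left 0 or 1 call, limma's own test gave 0 and edgeR 5, and a coverage minimum of 3 reads gave 20. Without an animal the differences stayed large, from 50.4 to 57.9 points in the first region, 47.3 to 55.9 in the second and -45.4 to -34.5 in the last, so it was the adjusted p that was lost. In simulated reads on these regions 26% of shifts of 40 points and 8% of shifts of 20 points were called.

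The authors' differentially methylated regions (DMRs) went mostly 1 way within each list, with lambs higher in the hyper list and lower in the hypo list. The list names do not say which stage is the reference, and hyper was read as higher in lambs. Of 526 autosomal hyper DMRs 148 could be tested, and 147 of these had the higher mean in lambs, with a median difference of 21.7 percentage points and quartiles of 15.7 and 27.1. Of 496 autosomal hypo DMRs 128 could be tested, and 125 had the lower mean in lambs, with a median difference of -22.3 points and quartiles of -26.5 and -16.2. The median SD between animals of a stage was 8.43 points in hyper and 8.82 points in hypo DMRs (n = 3 per stage). Adjusted over the DMR lists alone, 91 hyper and 82 hypo DMRs passed an adjusted p under 0.05 with at least 10 points in the direction of the list, and 0 in the opposite direction (quasi-binomial test with limma's moderation). The levels of the animals did not overlap between stages in 103 hyper and 88 hypo DMRs, where chance gives 10% over both directions. These lists were chosen on the same animals, so the counts are not independent evidence of a difference. A DMR had a median of 4 usable CpGs. Summed over those CpGs, the median was 37.8 reads per animal in hyper and 36.2 in hypo DMRs, so separate reads may be fewer. With a coverage minimum of 1 read 978 DMRs could be tested and 473 passed, and with a minimum of 3 reads 383 passed.

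Of the hyper DMRs 76.0% overlapped a fetal UMR or LMR and 35.4% a lamb one, with 214 at fetal regions alone, 0 at lamb regions alone, 186 at regions of both stages and 126 at neither. Of the hypo DMRs 70.8% overlapped a lamb UMR or LMR and 32.3% a fetal one, with 192 at lamb regions alone and 1 at a fetal region alone. Fetal DMVs were overlapped by 7 hyper DMRs, or 1.33%, and lamb DMVs by 6 hypo DMRs, or 1.21%. The DMV lists cover only 3.87 Mb in fetal and 3.40 Mb in lamb tissue, with X and unplaced contigs included. These small counts therefore do not show that DMRs avoid DMVs. The DMR, UMR and LMR lists come from the same 6 animals, and a DMR low in 1 stage is likely to be on that stage's list of low regions, so these overlaps are not independent of how the lists were made.

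Among tested hyper DMRs whose levels did not overlap, the largest difference, 43.8 points, was on chromosome 19 from 52073095 to 52073745, overlapping a UMR of both stages, at 2.09% ± 1.81 in fetal and 45.9% ± 23.3 in lamb animals (SD, n = 3 each). Its lambs ranged from 20% to 65.2% over 26.8 reads per animal. The hyper DMR on chromosome 24 from 24775227 to 24775847 was at 47.0% ± 8.28 and 86.0% ± 5.72 over 12 CpGs (SD, n = 3 each; adjusted p = 3.79e-06 over the DMR lists alone, with limma's moderation). On chromosome 13 from 50849370 to 50849788, overlapping a UMR of both stages, the fetal level was 6.63% ± 1.87 and the lamb level 41.5% ± 25.3, with lamb 2 at 69.6%. On chromosome 15 from 78337116 to 78337441, overlapping a fetal LMR, the levels were 36.4% ± 8.23 and 71.8% ± 1.75. The 10 largest differences in hyper DMRs without overlap of levels ran from 34.5 to 43.8 points.

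Among tested hypo DMRs whose levels did not overlap, the largest difference was on chromosome 19 from 50041365 to 50041424, overlapping a lamb UMR, at 79.4% ± 16.2 in fetal and 30.6% ± 8.90 in lamb animals. On chromosome 6 from 25948159 to 25948470, overlapping a lamb LMR, the levels were 85.6% ± 3.35 and 37.1% ± 21.5. On chromosome 15 from 37823638 to 37823933, overlapping a UMR of both stages, the lambs were at 1.67% ± 2.89 and the fetal animals at 37.5% ± 5.14. On chromosome 2 from 2191344 to 2191899, over 9 CpGs and 81 reads per animal, the levels were 48.7% ± 8.80 and 13.3% ± 1.78 (SD, n = 3 each; adjusted p = 2.88e-05 over the DMR lists alone, with limma's moderation). The hypo DMR on chromosome 7 from 97896640 to 97897330, which holds the UMR or LMR called lower in lambs, was at 68.4% ± 0.744 and 33.2% ± 9.66 over 14 CpGs. The 10 largest differences in hypo DMRs without overlap of levels ran from -48.7 to -35.1 points. Each of the 20 named DMRs passed the adjusted threshold with the 6 animals, and 1 of them lost it without fetal animal 3 and 1 without lamb 2. They were picked on these animals for large differences without overlap, so passing is not independent evidence. Adjusted over all 1 kb windows in the same test, no window passed. The window from 24775001 on chromosome 24 had an adjusted p of 0.0981, and that from 2191001 on chromosome 2 of 0.140.

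**Figure D2:**
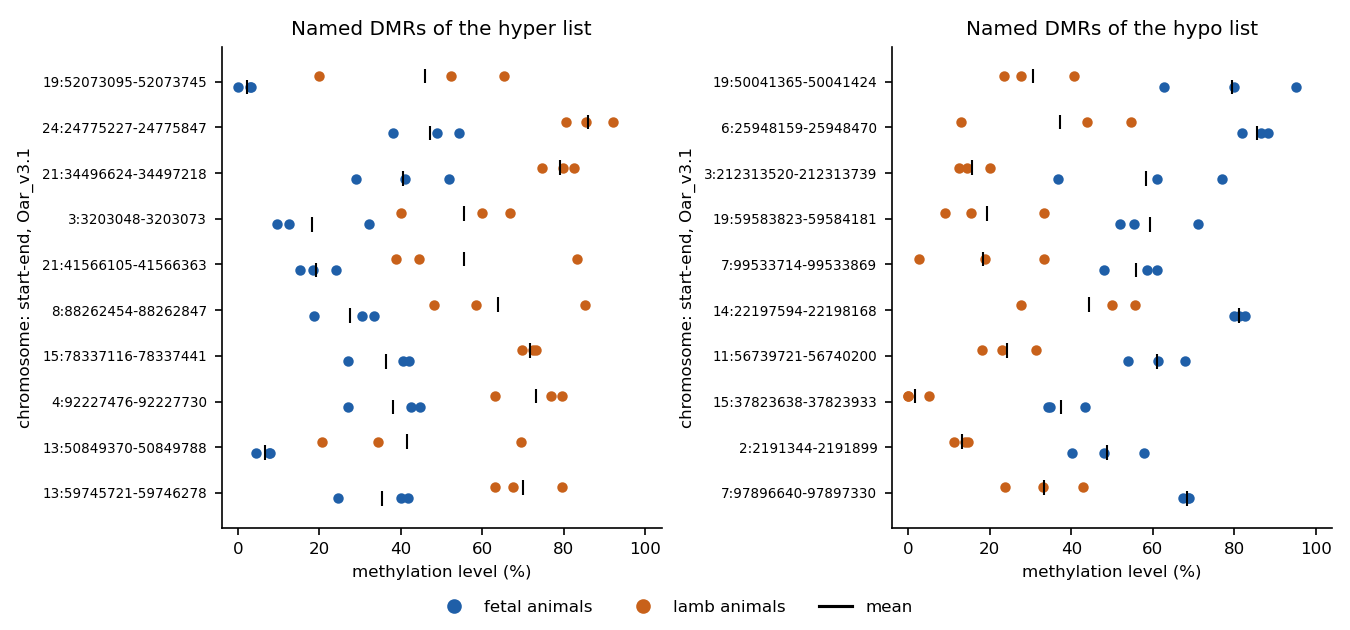
Methylation level in percent (x axis) of each fetal and lamb animal in the 10 hyper and 10 hypo DMRs with the largest differences among those whose levels do not overlap between stages (y axis, position on Oar_v3.1); points are animals and short vertical lines the means of 3 animals. The lamb points spread widely in some hyper DMRs, such as 20% to 65.2% on chromosome 19 from 52073095.

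The X chromosome was described and not tested, since sex is not in the labels. Its coverage relative to the autosomes was 0.927, 0.899 and 0.887 in fetal animals 1 to 3, and 0.936, 0.947 and 0.959 in lambs 1 to 3. The X methylation level was 64.9%, 65.4% and 64.9% in fetal animals, and 65.2%, 67.0% and 65.9% in lambs.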

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

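Reads on the mitochondrial genome, which no comparison uses, exceeded the 3 reads that a count of 0 allows in 3 of the 6 animals. Lamb 2 had 1492 CpG-covering mitochondrial reads at 7 positions, lamb 3 had 173 at 1 position and fetal animal 1 had 9 at 1 position.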

How the results depend on the processing

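The coverage minimum of 1 read, the tests without chromosome ends, those on regions listed in both stages, the dispersion below 1 and the test of single DMVs with its alternatives were chosen after seeing the data. The global, LMR, UMR and DMV differences kept their sign in each setting run, from 0.191 to 2.47, 1.12 to 2.05, 0.285 to 1.84 and 0.192 to 0.985 points, but 3 animals against 3 cannot pass 0.05. Outside the listed regions the difference of 0.427 points was -0.0408 without lamb 2 (highest without another animal 1.000; the cause was not tested). Called windows, 0 at first, numbered 142 and 103 with minimums of 3 and 1 reads, 25 in 2 kb windows, and 0 to 4 without an animal (4 without lamb 2, 3 without fetal animal 3). Called UMRs and LMRs, 3 at first, numbered 20, 30 and 0 with minimums of 3, 1 and 10 reads (the last over 562 regions), 0 with limma, 5 with edgeR, 0 when listed in both stages, 0 away from chromosome ends, and 0 to 1 without an animal. Called DMRs, 173 at first, numbered 383 and 473 with minimums of 3 and 1 reads, which let more DMRs be tested, 92 with at least 5 CpGs, over 120 DMRs, and 140 to 197 without an animal. DMVs with adjusted p under 0.05, 12 at first, numbered 44 and 65 with minimums of 3 and 1 reads, and 0 to 32 without an animal (0 without fetal animal 1, 32 without lamb 2). With 50% reciprocal overlap the shared part was 90.7% of fetal and 91.8% of lamb UMRs, 59.6% and 62.4% of LMRs, and 88.1% of lamb DMVs. Replicate numbers name separate animals. With the number as a replicate block, UMRs and LMRs gave 0 calls, windows 0, DMRs 180 and DMVs 4. Deviations of same-numbered animals correlated by 0.00391 to 0.0104 over windows and -0.000421 to 0.00752 over UMRs and LMRs, which does not pair them. Over the DMRs, which were selected on these animals, the same-numbered correlations were 0.1002, 0.146 and 0.189 and the others -0.124 to -0.0270. Each animal correlated best with its own number over windows and DMRs but not over UMRs and LMRs, a hint from the data and not from the design. Except where said, the cause of these changes was not tested. Too few DMRs and single DMVs could be tested with a minimum of 10 reads, and the promoter and gene list alternatives were not run.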

Other observations

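The tests in this part were chosen after the results were seen, except the share of p values in regions listed in both stages, with and without lamb 2, the matched windows near chromosome ends with their dispersion and splits, and the splits of single DMVs. Taken singly, 402 of 547 DMVs had a higher mean level in lambs, with a median difference of 0.825 percentage points, and the levels did not overlap in 113 that were higher and 28 that were lower, where chance gives 10% over both directions. In the quasi-binomial test with limma's moderation, 11 DMVs were higher and 1 was lower at an adjusted p under 0.05, with no minimum difference. The DMV on chromosome 15 from 60768851 to 60794750, with 311 usable CpGs, was at 4.51% ± 0.137 in fetal and 6.62% ± 0.270 in lamb animals (SD, n = 3 each). A second one nearby, from 61371851 to 61379350, was at 6.41% ± 0.826 and 9.62% ± 0.659. The DMV on chromosome 8 from 51779051 to 51786850 was at 6.01% ± 1.95 and 12.6% ± 1.73. The single DMV that was lower, on chromosome 21 from 42922151 to 42929750, was at 18.2% ± 3.04 in fetal and 7.51% ± 0.499 in lamb animals (adjusted p = 0.00907 with limma's moderation). The count was unsteady: 44 and 65 passed with coverage minimums of 3 and 1 reads, over 548 and 551 DMVs, and from 0 without fetal animal 1 to 32 without lamb 2 when an animal was left out. Of the 10 splits of the animals 1, the real one, gave 12 or more such DMVs, and the highest other gave 0, but 10 splits are too few to test chance at 0.05.

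Higher DMV methylation in lambs was set against incomplete bisulfite conversion, the way the lists were made, and a shift of DMV edges. Conversion failure would raise all unmethylated CpGs alike, but among regions under 5% methylated over the 6 animals, DMVs rose relative to UMRs by 0.390 points, with each lamb above each fetal animal (exact permutation p = 0.1), while the UMRs differed by -0.00569 points. The lamb list was not picked for low fetal levels, and its DMVs were higher in lambs by 0.690 points. That argues against selection as the whole cause, but 91.1% of these DMVs also overlapped a fetal DMV. The 41 DMVs on the lamb list alone were lower in lambs, at 6.38% in fetal and 5.30% in lamb animals. The 100 on the fetal list alone were higher in lambs, at 6.64% and 7.89%, so selection may be part of the rise. The middle 50% of the DMVs of both lists was higher in lambs by 0.763 points. This argues against edges as the whole cause but not against selection, since DMVs of the fetal list alone are included. The rise was not particular to DMV cores, since the outer 50% rose by 1.04 points and the 5 kb on each side by 1.07, with each lamb above each fetal animal (exact permutation p = 0.1). Chance is not excluded by these differences (exact permutation p = 0.1, the smallest value that 3 animals against 3 allow). Other differences between the fetal and the lamb animals, apart from stage, were not tested. With at least 10 reads in each animal the DMV difference was 0.192 points (exact permutation p = 0.8). A gain of DMV methylation with stage, which includes a change in the mix of cells of the depot, is therefore only a hypothesis. The design holds no test of it.

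More UMRs and LMRs had an unadjusted p under 0.05 between stages than in other splits of the animals. Selection of the lists may account for part of it, since the share was 21.2% in regions of 1 stage and 8.90% in those listed in both. The latter was still above the 9 other splits, whose highest was 6.03%. A merged region counted as listed in both when it overlapped any UMR or LMR of each stage. That keeps regions that are a UMR in 1 stage and an LMR in the other, so selection may remain in this share too. Without lamb 2 the share in those regions was 7.85%, against 6.78% for the highest other split of the 5 animals, so that animal alone does not account for it. The 10 splits are too few to test chance at 0.05: 1 gave 3 or more called UMRs and LMRs and the highest other gave 1. For DMRs 1 split gave 173 or more calls and the highest other gave 1. The DMR lists were chosen on these animals, so that outcome was set in advance and does not bear on chance. The real split called 0 windows, which every split must reach, and the highest other called 2. A stage difference spread thinly over many regulatory regions remains a hypothesis.

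The authors' DMRs were crowded toward chromosome ends, with 27.2% within 5 Mb of an end. The share was 11.1% of 1 kb windows with at least 3 CpGs read in each animal and 15.9% of the windows tested. It was 18.4% of the UMRs and LMRs tested. Windows matched on CpG number, depth and overlap with UMRs or LMRs gave 22.0% (95% of 10000 binomial draws between 19.6% and 24.3%, with p = 0.0001 from the draws, the smallest they can give). The draws took DMRs as independent, but DMRs crowd together, as on chromosome 20 below. The interval is therefore likely too narrow and the p too small. These 3 properties together may account for part of the excess, and whether they account for all of it is not settled. A larger spread between animals near ends stays open: the matched dispersion ratio was 1.036 (95% interval 1.026 to 1.046 over draws of chromosomes), under the bound of 1.05 set beforehand, but p values under 0.05 were more frequent near ends in each of the 9 other splits, by 0.144 to 0.444 points, which that bound did not foresee. A stage difference near ends cannot be told apart from it. The real split gave an excess of 0.0143 points, lower than each of the 9 other splits. By the rule set beforehand, that result counts against a stage difference near ends. But near-end DMRs amount to 0.205% of the near-end windows tested. This is less than the distance between the lowest and the highest of those splits, a limit that the rule did not foresee. By chromosome, with DMRs taken as independent, 70 lay on chromosome 20 where its CpGs predict 26.9 (binomial adjusted p = 3.16e-11) 66 on chromosome 11 against 39.4 (adjusted p = 0.000804), 125 on chromosome 3 against 94.4 and 18 on chromosome 9 against 35.8 (adjusted p = 0.00995 for both), and 14 lay between 49 and 50 Mb of chromosome 20, whose last CpG is at 51.2 Mb.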
